A study of Zea mays with 4 samples.

How the data were processed

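The 4 ChIP-seq libraries came from pericarp of near-isogenic P1-rr and P1-ww maize at 14 days after pollination, 2 libraries per genotype, all precipitated with polyclonal antibodies against P1. Per the labels' protocols, the tissue was fixed with formaldehyde, nuclei were enriched, chromatin was sonicated, and barcoded libraries were built from biological duplicates. Base calling used CASAVA version 1.4 and alignment used Bowtie, per the submitters' processing notes, which name the tools without their order. The peaks are named after MACS in the deposited lists. The MACS version and settings, the handling of duplicate reads and the genome build are not given in the sources used here.

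The deposited files were 2 peak lists without headers, each holding a chromosome, a start, an end, a name and a score per peak. Per the labels, each list belongs to 1 P1-rr library and the P1-ww library of the same number, so peaks were called by the authors per pair and not on pooled duplicates. The score is the peak caller's own value as deposited by the authors. Its scale is not stated in the files. It was used to describe, rank and filter peaks within a list, to compare medians there and to fit the repeated values. Across lists, score ranges were described side by side, ranks were averaged to choose the named regions, and scores were correlated over shared regions. No test compared the score level of the lists. Start positions were read as counted from 0 and are printed counted from 1. The lists give no reads, so library depth, enrichment folds and read counts per peak were not analysed here. Every value column of both lists was used, and 0 columns were left unmapped.

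Overlap was counted at 1 bp or more with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15, and bedtools 2.31.1 gave the same count of 456. A shared region is the union of the overlapping peaks. Chance overlap came from 100000 random placements of the list 2 peaks on their own chromosomes with widths kept (10000 for alternatives, 2000 for overlap of 50% of both peaks and for distances). The extent of a chromosome was the largest peak end in either list, 301295526 on chromosome 1. Expected overlap by score or width used each peak's own width. Medians of scores were compared by permutation with 100000 resamples, two-sided. Densities per chromosome were tested with a chi-square statistic against 100000 multinomial draws. The donor segments, whose borders are given in the labels on build AGPv2, were compared with the rest of their chromosome by circular shifts. The largest peak positions do not go against that build, but no source here states that the lists use it. Shares carry Wilson intervals and counts exact Poisson intervals, at 95%, from scipy 1.17.1. They cover counting error only. Adjusted p-values are Benjamini-Hochberg over the 2 score tests, the 3 chromosome tests, the 6 segment tests and the 3 tests of chromosome middles. Figures were drawn with matplotlib 3.10.9.

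The regions named were fixed by rule before the data were examined: with no annotation of the right build, the 20 shared regions with the best mean rank of score. The tests of overlap, of score, of chromosomes and of donor segments were fixed then too, with most alternatives. The comparisons by distance, by peak width and by class of score, and that of chromosome middles with outer parts, were not among them. The tests of placement treat peaks as independent and describe these lists, not the spread between further plants. Alternatives covered the overlap definition, the score threshold, the list length, the form of random placement, each duplicate alone and the background of the segments. The planned comparisons of peaks with gene annotation, of flavonoid, phenylpropanoid, regulator and control gene lists, and of the P1 binding motif were not run, because no genome or annotation of the files' build was used here. The gene table at hand describes assembly Zm-B73-REFERENCE-NAM-5.0, and its coordinates were not used.

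The overlap and segment computations were tested on simulated data. With no shared sites, 0 of 20 simulated lists gave p under 0.05. These lists were placed by the same rule as the random placements, so this checks the computation only. It does not cover the uneven spread of peaks in the real lists. With 200 planted sites among 14719 list 2 peaks, the mean excess recovered over 10 simulated lists was 198.1. The P1-rr and P1-ww libraries share replicate numbers, and the lists were made within these numbers.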

Results

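Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the maize transcription factor P1 sits on the genome. P1, encoded by pericarp color1, is an R2R3-MYB regulator of flavonoid pigments known for the red phlobaphenes of the pericarp, the maternal layer that covers the kernel. The antibody was raised against P1, and the tissue was pericarp at 14 days after pollination. A total of 4 libraries was made, 2 from P1-rr plants, which express P1 in the pericarp, and 2 from near-isogenic P1-ww plants, which do not. The P1-ww libraries carry the background of the antibody, so the question was which sites are enriched in P1-rr over P1-ww. The data consisted of 2 peak lists. List 1 set P1-rr replicate 1 against P1-ww replicate 1, and list 2 set P1-rr replicate 2 against P1-ww replicate 2. The protocol describes biological duplicates. The peaks were called by the authors within each pair, and each peak carries a position and a score, which is the authors' own. The read depth of the libraries is unknown here, so intervals cover the counting of peaks only.

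Enriched sites were called across the whole genome in both duplicates, on all 10 chromosomes, in unplaced sequence and in the mitochondrial genome. List 1 held 20424 peaks and list 2 held 14719, a ratio of 1.39. The peaks were short and covered little sequence, with 4220 kb in list 1 and 5417 kb in list 2. The lists differed in the shape of their peaks. In list 1, 95.5% of peaks (95% Wilson interval 95.2 to 95.8) were exactly 200 bp wide, the smallest width in either list. In list 2 that share was 29.8% (29.1 to 30.6), the median width was 332 bp (interquartile range 200 to 488), and the widest peak, in the mitochondrial genome, measured 3615 bp. Scores also lay on different ranges, with a median of 282.63 in list 1 (interquartile range 152.6 to 672.49) and 70.05 in list 2 (51.96 to 111.47). Few distinct scores occurred in list 1: 538 values served 20424 peaks, and the 10 commonest accounted for 67.5% of them, against 20.5% in list 2. A total of 962 list 1 peaks scored 3100 or more, while the highest score in list 2 was 2475.57. Exactly 3100 was the score of 932 of the 962, so the score does not order those 932 peaks. Narrow peaks of list 2 scored higher than wide ones, with medians of 116.93 at 200 bp and 58.23 above it.

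**Figure D1:**
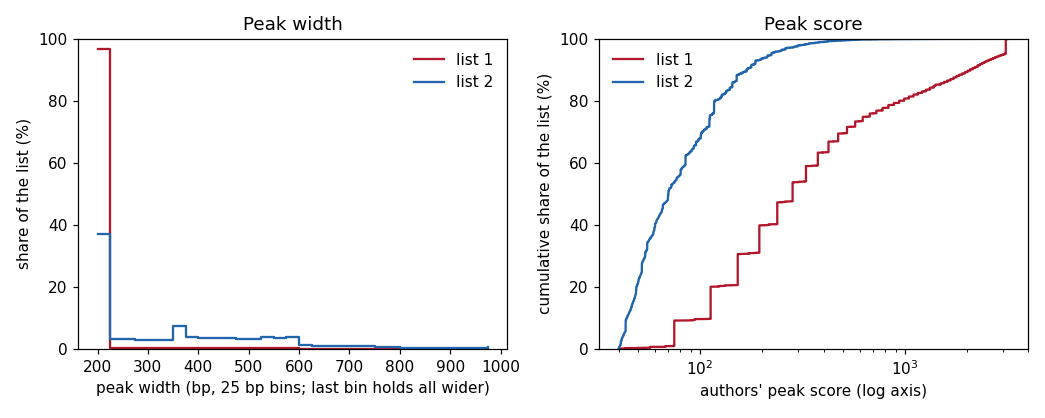
Peak width (left, x axis in bp, y axis in percent of the list) and the authors' peak score (right, log x axis, y axis the cumulative percent of the list) for list 1 (red) and list 2 (blue). Almost all list 1 peaks lie in the narrowest bin and its scores climb in steps, while list 2 spreads over wider peaks and lower scores.

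The duplicates shared few sites, although more than random placement gave. Of the list 1 peaks, 456 overlapped a list 2 peak by at least 1 bp, which is 2.23% of the list (95% Wilson interval 2.04 to 2.44). Of the list 2 peaks, 453 overlapped list 1, or 3.08% (2.81 to 3.37). These formed 453 shared regions with a median length of 512 bp. When the list 2 peaks were placed at random on their own chromosomes, a mean of 83.6 list 1 peaks overlapped (SD 9.10 over 100000 placements, 95% range 66 to 102). The observed overlap was 5.46-fold higher (one-sided permutation p = 1e-05, the smallest that this number of placements can give). The placements could fall anywhere in the span of a chromosome. Where reads can align was not examined, so the excess is not by itself a measure of shared P1 binding. The remaining 19968 list 1 peaks and 14266 list 2 peaks had no counterpart in the other duplicate. The count depended on the definition of a shared site: 109 list 1 peaks shared at least 50% of both peaks, 204 had a list 2 centre within 100 bp of their own, and 824 lay within 500 bp of a list 2 peak.

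Peak centres of the duplicates lay close to each other more often than random placement gave, overlapping peaks included. Peak centres of list 1 had a nearest list 2 centre within 250 bp in 387 cases against 72.8 under random placement, a 5.31-fold excess. The excess was 2.93-fold from 250 to 500 bp, 2.31-fold from 500 to 1000 bp, 1.59-fold from 1000 to 2000 bp and 1.42-fold from 2000 to 5000 bp (two-sided permutation p = 0.001 in each distance class, the smallest that 2000 placements can give). From 5 to 10 kb it was 1.14-fold (permutation p = 0.001) and from 10 to 20 kb 1.06-fold (permutation p = 0.0050, 2489 pairs against 2353). From 20 to 50 kb there were fewer nearest centres than under random placement, 4990 against 5340 (0.934-fold, permutation p = 0.001). Every list 1 peak was counted only at its nearest list 2 centre, so an excess at short distances forces a deficit further out. This deficit is not a separate result. Moving all of list 2 by a constant distance of more than 5 kb left a median of 99 overlapping list 1 peaks and at most 135, above the 83.6 of random placement and below the 456 of the unshifted lists.

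**Figure D2:**
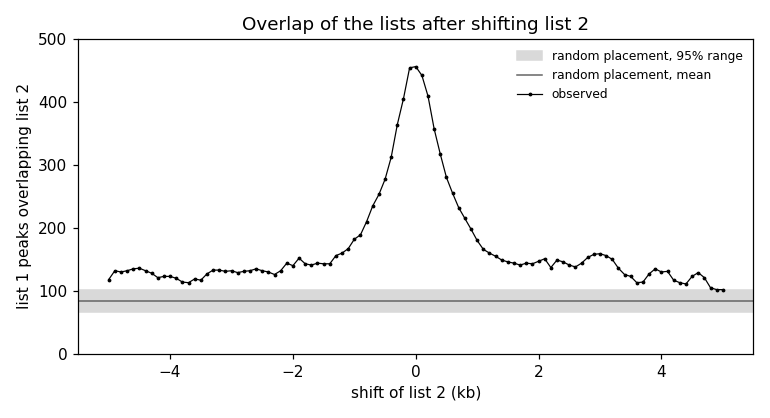
Number of list 1 peaks that overlap a list 2 peak (y axis) after list 2 was moved by the distance on the x axis (kb), with the mean and 95% range of random placement in grey. The count is highest at 456 with no shift and has fallen to 182 at a shift of -1 kb.

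Higher-scoring sites were not shared more often than lower-scoring ones. In list 1, 1.67% of the highest-scoring 10% of peaks were shared against 2.49% of the lower-scoring 50%, a ratio of 0.669 (95% range of resampled counts 0.447 to 0.919). In list 2 the shares were 1.5% and 3.76%, a ratio of 0.397 (0.227 to 0.584). After each peak's own chance of overlap, which grows with its width, was taken into account, the ratios were 0.670 (0.448 to 0.920) in list 1 and 0.600 (0.344 to 0.882) in list 2. Shared list 2 peaks scored lower than the others, with medians of 60.67 and 70.05 (difference -9.38, two-sided permutation p = 0.0055, adjusted p = 0.011). They were also wider, with medians of 468 and 326.5 bp, and within classes of similar width the score difference was -5.61 (permutation p = 0.0082). Where sharing was defined by 50% of both peaks, the difference of medians without classes of width was -0.35 (permutation p = 0.87). In list 1 the medians were 237.92 and 282.63, and the difference of -44.71 did not pass the test (permutation p = 0.15). Across the 453 shared regions the scores of the lists were not related, with Spearman's rho of -0.036 (bootstrap 95% range -0.12 to 0.060, permutation p = 0.44) and Pearson's r of -0.025 on log10 scores (permutation p = 0.59). These are correlations across regions, which are not independent replicates. In list 2 wide peaks were shared more often than narrow ones: 400 of 10326 peaks wider than 200 bp were shared, 6.07 times the number expected for their width (exact Poisson 95% interval 5.49 to 6.70). Of the 4393 peaks of 200 bp, 53 were shared, 3.00 times the expected number (2.25 to 3.93), and this 2.02-fold difference was larger than counting error (exact binomial p = 2e-07).

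**Figure D3:**
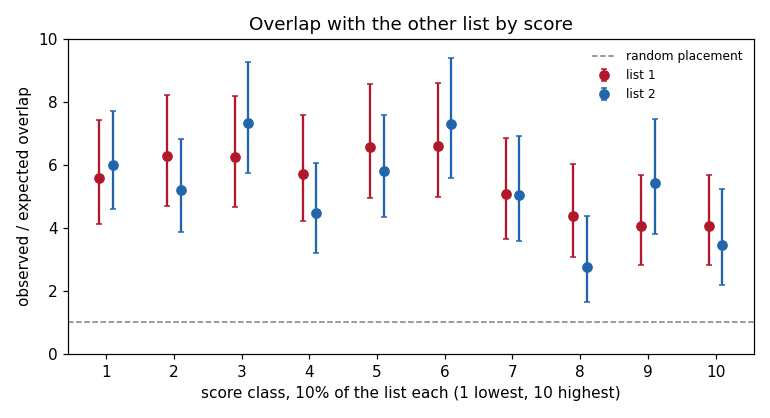
Observed over expected overlap with the other list (y axis) for 10 classes of score that each hold 10% of a list (x axis, 10 the highest), with exact Poisson 95% intervals, for list 1 (red) and list 2 (blue). Every class lies above the dashed line of random placement at 1, and the highest class lies at 4.07 in list 1 and 3.47 in list 2, against 5.59 and 6.01 in the lowest.

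The 20 shared regions with the best mean rank of score lay on 7 chromosomes, with 5 on chromosome 5, 4 on chromosome 1, and 3 each on chromosomes 3 and 8. They were 211 to 1110 bp long (median 380). A list 1 score of 3100 was tied over 932 peaks, which therefore shared a rank. The region that ranked first was at positions 48971974 to 48972301 of chromosome 3, where the list 1 peak scored 3100 and the list 2 peak 249.45. The next was also on chromosome 3, at 28479956 to 28480174, with scores of 2685.01 and 441.73. The third was at 143439541 to 143439899 of chromosome 4 (3100 and 168.85), the fourth at 126970483 to 126970693 of chromosome 1 (2258.12 and 222.87), and the fifth at 210766427 to 210766820 of chromosome 5 (2500.96 and 175.58). The peaks of the lists overlapped by 72 bp in the first of these regions, 187 bp in the second and 56 bp in the third. In the fourth they overlapped by 189 bp and in the fifth by only 6 bp. The highest list 2 score among the 20 was 573.53, at 75989862 to 75990183 of chromosome 8, where list 1 scored 570.75. A second region of chromosome 8, at 76155071 to 76155699, lay on the same part of the chromosome, with scores of 2379.16 and 86.76. Of the 20 regions, which were chosen by score, 5 were in the highest-scoring 10% of both lists. Over the whole lists, 5 list 1 peaks of the highest-scoring 10% overlapped a list 2 peak of that class. Random placement gave a mean of 0.617 such peaks (permutation p = 0.0006), a test of the lists and not of the 20 regions. Only 3 of the 20 had a pair of peaks that overlapped by 50% of both. None of the 20 lay in a donor segment of the near-isogenic lines. Positions are those of the lists, with starts changed from counting from 0 to counting from 1. The genome build is not given in the sources used here, so no gene, exon or promoter is assigned to these regions.

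Peak density differed little between chromosomes, with chromosome 4 the densest and chromosome 2 the sparsest in both duplicates. Density was measured against the span of peak positions, since chromosome lengths of the build were not used here. List 1 had 9.90 peaks per Mb over the 10 chromosomes, from 9.25 on chromosome 2 (exact Poisson 95% interval 8.87 to 9.64) to 10.9 on chromosome 4 (10.5 to 11.3). List 2 had 7.12 per Mb, from 6.56 on chromosome 2 (6.24 to 6.90) to 8.26 on chromosome 4 (7.90 to 8.63). Both lists departed from even density (chi-square of 65.6 and 65.5, permutation p = 1e-05 each, the smallest that 100000 draws can give, adjusted p = 2e-05). These draws and intervals treat peaks as independent. Counts per 1 Mb window had a variance of 19.96 around a mean of 9.9 in list 1, and 12.4 around 7.11 in list 2. The p-values are therefore too small and the intervals too narrow. Chromosome 4 held the densest complete 5 Mb window of each list, at different places. In list 1 it was 115 to 120 Mb, with 104 peaks against 65 in list 2, and in list 2 it was 50 to 55 Mb, with 82 peaks against 80 in list 1. Shared regions numbered 449 on the 10 chromosomes, 0.218 per Mb, and their spread from 0.179 per Mb on chromosome 9 to 0.253 on chromosome 5 was within chance (chi-square of 4.46, permutation p = 0.88).

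**Figure D4:**
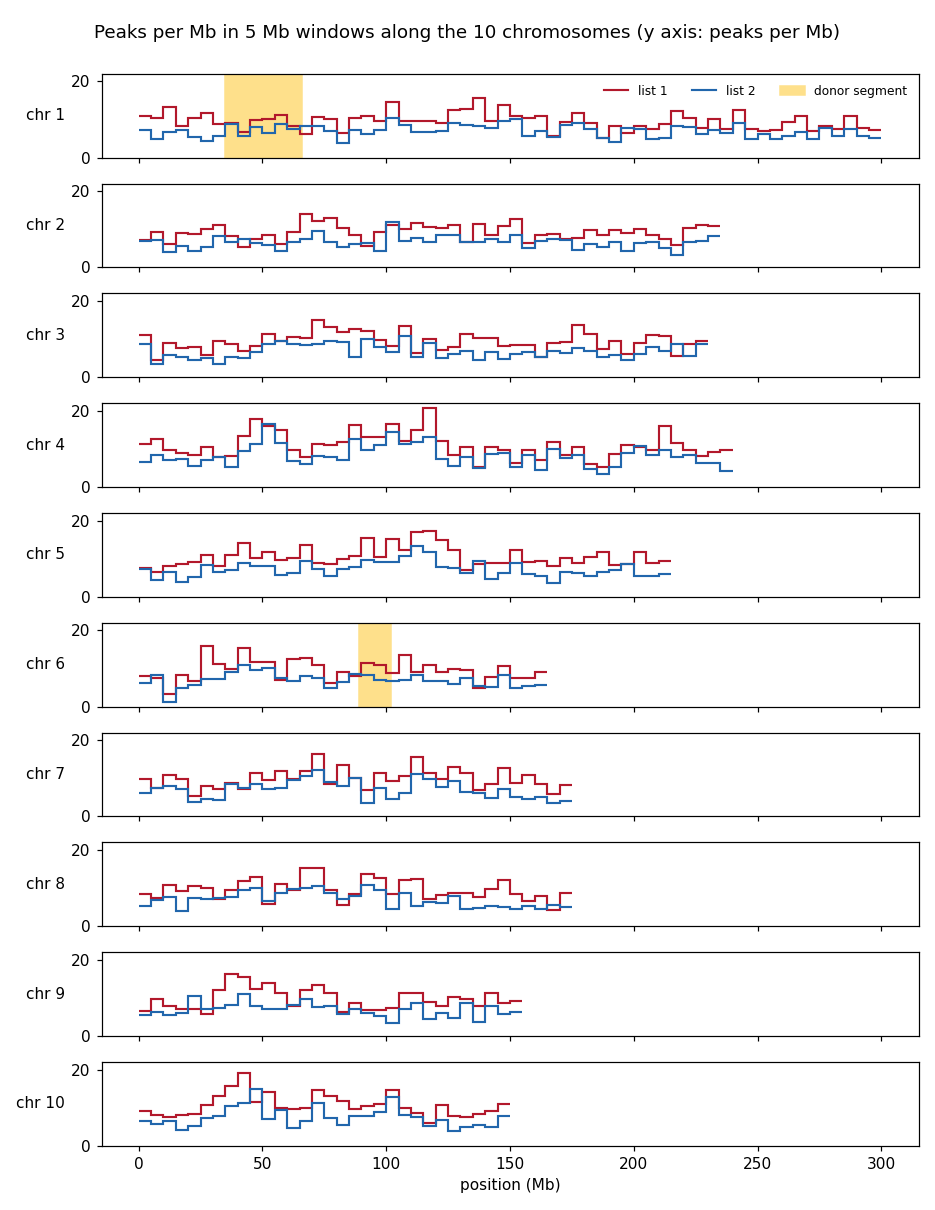
Peaks per Mb (y axis) in complete 5 Mb windows along each of the 10 chromosomes (x axis, Mb) for list 1 (red) and list 2 (blue), with the donor segments shaded. The highest window reaches 20.8 peaks per Mb in list 1 and 16.4 in list 2, both on chromosome 4, and the windows in the donor segments stay below these.

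The near-isogenic lines differ in sequence as well as in P1, because the P1-rr line carries donor DNA on chromosome 1 from 35 to 66 Mb, which holds the introgressed P1-rr allele, and a second piece on chromosome 6 from 89 to 102 Mb. Peaks were neither more nor less dense in these segments than elsewhere on their chromosomes, within the spread of segments of the same length. On chromosome 1 the donor segment held 282 list 1 peaks, 9.10 per Mb against 9.60 on the rest of the chromosome (ratio 0.947, circular-shift permutation p = 0.81). It held 237 list 2 peaks, 7.65 against 6.85 per Mb (ratio 1.12, permutation p = 0.45). Segments of that length moved along the chromosome held 7.71 to 12.2 list 1 peaks and 5.81 to 8.42 list 2 peaks per Mb in 95% of positions. On chromosome 6 the segment held 125 list 1 peaks (9.62 against 9.51 per Mb, ratio 1.01, permutation p = 1.0) and 90 list 2 peaks (6.92 against 6.94, ratio 0.998, permutation p = 0.93). Shared regions were few: 10 in the chromosome 1 segment (0.323 against 0.229 per Mb, ratio 1.41, permutation p = 0.44) and 4 in the chromosome 6 segment (0.308 against 0.211, ratio 1.46, permutation p = 0.58). None of the 6 permutation tests passed after adjustment (adjusted p = 1.0 for each). Set against 5 Mb on either side, a background chosen after seeing the data, the ratios of shared regions were 3.23 on chromosome 1 and 0.615 on chromosome 6 (two-sided exact binomial p = 0.32 and 0.52). The segment borders are given on build AGPv2, and the comparison takes the lists to use it. Of the shared regions in the segments, the best ranked was at 47598709 to 47598942 of chromosome 1, with scores of 471.53 and 175.51, followed there by 60799402 to 60800189 (375.29 and 148.96). On chromosome 6 it was at 91218607 to 91218937, with scores of 423.01 and 186.19. These 3 regions were picked after their values were seen. In simulated lists of the size of list 2, a segment made 1.5 times denser was called in 48 of 50 runs on chromosome 1. On chromosome 6 it was called in 38 of 50. The simulated positions were spread evenly, while real list 2 counts per 1 Mb window had a variance of 12.4 around a mean of 7.11. These runs therefore overstate what the tests could detect, and a segment 1.5 times denser could also pass unseen.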

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

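Peaks outside the 10 chromosomes took no part in the density comparisons and were looked at because any number above 3, the limit that a count of 0 allows, counted as a signal. No test was run on them and no explanation was weighed. The mitochondrial genome held 5 list 1 peaks and 29 list 2 peaks. Over the span of mitochondrial positions this was 8.92 per Mb in list 1 (exact Poisson 95% interval 2.90 to 20.8), close to the 9.90 of the chromosomes. In list 2 it was 51.7 per Mb (34.6 to 74.3), 7.27 times the 7.12 of the chromosomes. List 2 peaks covered 4.82% of that span against 0.261% of the chromosomes, with a median width of 542 bp. In each list 2 mitochondrial peaks overlapped the other list. Unplaced sequence held 46 list 1 and 43 list 2 peaks, 6.59 and 6.16 per Mb, and 2 of each list overlapped the other.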

How the results depend on the processing

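A total of 40 alternative values was computed, and those with peaks set to 200 bp, with wide list 2 peaks only and with 5 Mb flanks were chosen after seeing the data. The excess of overlap over random placement stayed between 3.61-fold and 8.10-fold in all alternatives run, with permutation p of at most 0.0006. Each alternative placed or shifted list 2 over the whole span of a chromosome, so none covers where reads can align. The count of overlaps moved with the definition, to 109 (50% of both peaks), 204 (centres within 100 bp), 824 (within 500 bp), 76 (higher-scoring 50% of each list, 10212 and 7360 peaks by construction) and 5 (highest-scoring 10%). The lower score of shared list 2 peaks lost its call with 50% overlap (-0.35, permutation p = 0.87); the cause was not tested. The correlation of scores, never called, turned to 0.10 in the higher-scoring 50%; the cause was not tested. The highest-to-lowest density of chromosomes, not called for shared regions (1.41), was called for each list alone, at 1.18 to 1.26, where many more peaks were counted, and was 3.62 in the higher-scoring 50% (76 peaks, permutation p = 0.073). The segment ratios, never called, were 0.947 to 1.12 on chromosome 1 and 0.998 to 1.01 on chromosome 6 for single lists, and 3.23 and 0.615 against flanks. On chromosome 6 the ratio was 6.00 in the higher-scoring 50% and 2.08 for covered base pairs. The cause was not tested. Of the 40 values, 21 kept the direction and the side of the threshold, or a count within 1.5 times. The shared count has no value from a single list, and the score comparison within equal-sized classes of width could not be made in list 1, where 95.5% of peaks have one width. The annotation, gene list and motif alternatives were not run. No paired analysis was possible because each list already sets 1 P1-rr library against the P1-ww library of its number and holds no value per library. Shared regions on a single chromosome are few, so modest differences between segments cannot be seen.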

Other observations

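The tests of the score steps, of overlap among wide peaks and of 1 Mb windows were chosen after the results were seen, and the comparison of chromosome middles was not planned at the start. Peaks of both lists were denser in the middle of chromosomes, from 25% to 75% of their span, than in the outer parts. The ratio was 1.16 in list 1 (middle higher on 10 of 10 chromosomes, exact two-sided sign-flip permutation p = 0.0020, adjusted p = 0.0029) and 1.21 in list 2 (10 of 10, exact permutation p = 0.0020, adjusted p = 0.0029), the smallest p that 10 chromosomes can give. For shared regions it was 1.38 (higher on 9 of 10 and equal on 1, exact permutation p = 0.0039, adjusted p = 0.0039). Shared regions are overlaps of 2 lists that are each denser in the middle, so their ratio is not separate evidence. Chromosomes 7 and 10 had the highest ratios in list 2, at 1.42 and 1.51, and in list 1, at 1.30 and 1.31. Maize genes, as background, are denser towards chromosome ends. A stretch of chromosome 6 from 10 to 15 Mb was the poorest complete 5 Mb window of both lists, with 17 peaks in list 1 and 6 in list 2. The densest 1 Mb window over both lists was 69 to 70 Mb of chromosome 8, with 19 list 1 and 24 list 2 peaks.

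The middle excess was weighed against weak peaks, narrow peaks and the donor segments. Weak peaks are argued against as the whole cause in both lists, and narrow peaks in list 2. In the higher-scoring 50% the ratio was 1.24 in list 1 and 1.158 in list 2, and among list 2 peaks wider than 200 bp it was 1.27. Without chromosomes 1 and 6 it was 1.168 in list 1 and 1.23 in list 2. Donor segments cannot cause an excess on chromosomes that lack them, and the middle was denser on 10 of 10 chromosomes. Leaving chromosomes 1 and 6 out is therefore no separate support. How uniquely reads align along the chromosomes was not examined here and stays open, as does binding by P1.

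Counts per 1 Mb window of the lists were correlated (Pearson's r = 0.456, Spearman's rho = 0.446 across 2053 windows), above all of 2000 circular shifts of list 2 (highest r 0.164, permutation p = 0.0005, the smallest these shifts can give). This argues against chance placement within chromosomes. Windows are not independent replicates.

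The small overlap of the duplicates was weighed against weak peaks, an offset of coordinates and narrow peaks; no biological explanation was tested, as the lists repeat the same comparison. Weak peaks as ranked by score are argued against in list 1, though the score may not rank binding strength. There the highest-scoring 10% were shared at 0.669 times the rate of the lower-scoring 50%. In list 2 that ratio was 0.397, or 0.600 after each peak's own chance of overlap was taken into account. Of the higher-scoring 50% of list 2, 54.5% were 200 bp wide, against 5.2% of the lower-scoring 50%. Narrow list 2 peaks were shared less often for their width, so the list 2 ratio mixes score with width. A constant offset is argued against, since the shifts from 1 to 100 kb tried gave at most 182 overlaps against 456. Narrow peaks as the whole cause are argued against, since 2.40% of list 1 peaks wider than 200 bp (95% Wilson interval 1.59 to 3.61) met a wide list 2 peak. That share concerns width only. Stacked reads in list 1 stay open as an explanation. Wide list 1 peaks had 0.929 times the observed over expected overlap of narrow ones (0.563 to 1.33), below the size predicted in advance. The range is too wide to exclude a lesser effect, and in list 2 wide peaks were shared more often. The comparison also takes wide list 1 peaks to be free of stacked reads, which was not examined. Their median score was 260.13, against 282.63 for narrow ones, so the comparison cannot decide.

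The repeated scores of list 1 may be whole read counts seen through a Poisson tail. Of 19393 list 1 scores under 3000, 96.3% lay within 0.01 of minus 10 times the log10 of a Poisson tail at a whole count, with the single rate of 0.0843, while the best of 1000 random rates reached 10.9%. The rate of 0.0843 was found by a search for the best fit, and the random rates were not. The 10.9% is therefore not the chance level of such a search. The fitted counts moved in steps of 2 for 97.6% of these scores, and in list 2 the best single rate, 0.213, took in 15.8% of scores, of which 74.3% lay on even counts. A candidate explanation is that narrow list 1 peaks hold stacked reads over an empty local background. Whether amplified copies, paired strands or a doubled input lie behind the steps was not tested, the scale of the score is inferred from the fit, and no biological explanation was tested.

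A hypothesis that sequence differences between donor and recurrent parent change peak density by over 25% was tested in the donor segments. The ratio farthest from 1 in either segment and list was 1.12, on chromosome 1 in list 2, and its counting interval of 0.978 to 1.27 reaches past that size. The other counting intervals lie within it, at 0.840 to 1.06 (chromosome 1, list 1), 0.842 to 1.21 (chromosome 6, list 1) and 0.803 to 1.23 (chromosome 6, list 2). These leave out the spread along a chromosome: segments moved along chromosome 6 held 4.38 to 10.5 list 2 peaks per Mb in 95% of positions, around 6.94 on the rest of it. The explanation needed every ratio to differ in one direction by over 25%, which no ratio did, but with that spread it stays open.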
